A study of Mus musculus with 8 samples.

How the data were processed

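RNA of 4 wild-type mouse stem cell lines was measured by RNA sequencing in 8 libraries, replicates 1 and 2 of each of ESC, TSC, XEN and EPISC. Per the labels' protocols, total RNA was taken with an RNeasy kit, and libraries were made from 1.3 micrograms of it with a TruSeq RNA kit. The culture and treatment protocols in the labels describe the adipogenic differentiation of a mesenchymal line that is not among the 8 libraries, so the culture conditions of the 4 lines are not given in the sources used here. The deposited values are raw read counts per gene symbol, whole numbers with 1 column per library. Per the submitters' processing notes, TopHat2, SAMtools, HTSeq and DESeq were used with the mouse builds GRCm38 and mm10, with no versions and no order of steps. The annotation release and the strand setting of the counting are not given in the sources used here. Reads from overlapping genes and from a gene and its antisense partner therefore cannot be told apart, which applies to Xist, Igf2r, Meg3, Mirg and their neighbours. Genes that share reads with close copies are uncertain, which applies to the placental prolactin, cathepsin, serpin, Rhox and Gbp2 families, to Hspa1a and Hspa1b, to Gapdh, Pgk1, Pgam1 and Eno1, and to ribosomal protein genes.

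The table held 26742 genes, of which 4559 had no count in any library, and no summary lines or further sample columns. The 13 mitochondrial genes were listed at 0 in all 8 libraries. Totals ranged from 12885798 to 27391811 counts per library. Symbols were matched to the GENCODE M21 annotation of GRCm38 for positions and biotypes, with 26638 matched and 23 having several identifiers. After the filterByExpr function of edgeR, with a minimum count of 10, 16169 genes were tested, 16154 of them with a position. Libraries were scaled by TMM factors, which ranged from 0.816 in XEN replicate 1 to 1.13 in EPISC replicate 2. Each line was set against each other line with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3. All 8 libraries entered 1 fit with the line as the only term, which left 4 residual degrees of freedom, a prior of 4.90 degrees and a common biological coefficient of variation of 12.8%. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 within the comparison and an absolute log2 fold change of at least 1. A signature was the set of genes called higher in a line than in each of the other 3, and the shared sets were genes called higher in both ESC and EPISC than in both TSC and XEN, or the reverse. CPM are counts relative to the library size scaled by TMM factors, and log2 CPM for the correlations and principal components used a prior count of 2.

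A fold against a line with no count is a lower bound that sets that line at 3 counts over its libraries. With 1 to 3 counts in the lower line, the ratio is given with an exact 95% binomial interval. Bounds and intervals cover counting error only. The 28 gene lists, with 373 genes, were fixed from general knowledge before the data were examined. Of these genes 365 were in the table and 316 were tested. Lists with at least 3 tested members, 26 in all, were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, beside camera with an estimated correlation and fry. The lists were shared, naive, and formative and primed pluripotency genes, primitive streak, trophoblast stem cell, differentiated trophoblast, primitive endoderm, parietal endoderm and visceral endoderm genes, and genes of DNA methylation, chromatin architecture, imprinting, the germline, the 2-cell-like state, fibroblasts and feeder cells, adipocytes, neural cells, mesoderm, Hox, FGF-ERK feedback, WNT targets, NODAL and TGF-beta targets, epithelial and mesenchymal cells, glycolysis, the immediate early and stress response, the mitochondrial genome, and X inactivation with the Y chromosome.

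Genes to be named were also set before the data were examined. In each direction of a comparison they were the 8 called genes with the largest fitted fold change and at least 50 CPM in the higher line, and for each signature or shared set the 10 with the largest minimum fold change and at least 50 CPM in its lines. From each list they were the members with the largest fold changes and the called members that went against the majority. Other list members named for their known roles were chosen after their values were seen. The edgeR test was run on counts simulated for TSC against ESC over 16169 genes, where 64.2% of genes changed 2-fold passed the adjusted p and 35.8% were called, with 88.1% of those changed 4-fold and 93.9% of those changed 8-fold called, and 3 false calls. In the same simulation camera called the changed list and 0 of 25 unchanged lists. Genes were simulated independently of each other, so this does not test whether the preset correlation is high enough for the real lists. Only 67, 67 and 66 genes were changed 2-fold, 4-fold and 8-fold, in TSC alone. In the real comparisons 37.4% to 54.5% of genes were called, so the simulation does not test the scaling where many genes differ. Overlap with no difference between lines was simulated 20 times.

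Alternatives fixed before the data were examined were the size factors of DESeq2 in edgeR, total counts alone, no count filter, a filter of at least 1 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, a fit of only the 4 libraries compared, adjusted p alone, glmTreat for a log2 fold change above 1, adjustment over all 6 comparisons, robust quasi-likelihood, the replicate number as a block, library sizes without the 50 highest genes, and leaving out each library. For signatures they were a log2 fold change of at least 2 and the signatures of ESC, TSC and XEN without EPISC. Removal of each library's trend with the GC content of the transcripts was added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No library was left out of the main tests. A comparison of 2 libraries with 2 allows no permutation test that could reach a p below 0.05.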

Results

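RNA from 4 mouse stem cell lines was sequenced in 8 libraries, 2 per line, and counted per gene. The lines stand for the cell types that part from each other in the early embryo. Embryonic stem cells (ESC) represent the pluripotent inner cell mass, trophoblast stem cells (TSC) the precursors of the placenta, and extraembryonic endoderm stem cells (XEN) the primitive endoderm that lines the yolk sac. The fourth line carries the name EPISC, and its labels call it an epiblast-like stem cell, the pluripotent state that follows the inner cell mass. The stated purpose was to describe each line and to compare the lines for the genes that mark them, so each line was set against each other line in 6 comparisons, and the genes higher in a line than in the other 3 were collected as its signature. The libraries held 13489137 and 12885798 counted reads for ESC, 26432347 and 20177081 for TSC, 17106340 and 27391811 for XEN and 19730825 and 20621245 for EPISC. Levels are given as CPM, the count relative to the library size scaled by TMM factors, as the mean ± SD of the 2 libraries of a line. A gene was called when its edgeR adjusted p was below 0.05 and its absolute log2 fold change was at least 1. A log2 fold change is given ± an approximate standard error, also where it stands alone in parentheses after a gene. It is positive when the line named first in the comparison was higher. The standard error is the absolute log2 fold change divided by the square root of the F statistic, and is too small where a line has few counts. For Cubn in XEN against ESC, with 5 counts in ESC, counting error alone gave a 95% interval of 1936 to 13915 for the ratio. In all, 16169 genes were tested, and positions refer to GRCm38.

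The 4 lines were separated by the genes that each is known for. Pou5f1, the transcription factor OCT4 that maintains pluripotency, stood at 486 ± 10.5 CPM in ESC and 354 ± 1.28 CPM in EPISC, against 4.89 ± 0.658 CPM in TSC and 0.2004 ± 0.223 CPM in XEN. Cdx2, a homeobox factor of the trophectoderm, reached 131 ± 7.62 CPM in TSC and at most 0.261 CPM in another line. Sox17, a factor of the primitive endoderm, reached 434 ± 3.22 CPM in XEN and at most 4.81 CPM in another line. Fgf5, a growth factor of the epiblast after implantation, reached 54.6 ± 0.616 CPM in EPISC and at most 0.118 CPM in another line. Across genes, the log2 CPM of the 2 libraries of a line correlated with Pearson r between 0.991 and 0.995, and libraries of different lines with r between 0.772 and 0.847. These coefficients run across genes, which are not independent replicates. The first principal component held 49.3% of the variance and set XEN apart, the second held 25.7% and set ESC apart, and the third held 22.5% and separated TSC from EPISC. Replicate libraries differed by more than counting noise in every line, with a chi-square per gene of 2.22 in ESC, 30.2 in TSC, 46.4 in XEN and 7.96 in EPISC, which does not tell repeat preparations of a culture from separate cultures. The labels do not say that the 2 libraries of a line came from separate cultures, and the p-values therefore measure a spread between libraries that may be technical. Each cell type was represented by a single line whose culture conditions are not given. A difference between lines therefore cannot be assigned to the cell type apart from the individual line, its culture or its sex chromosomes.

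**Figure D1:**
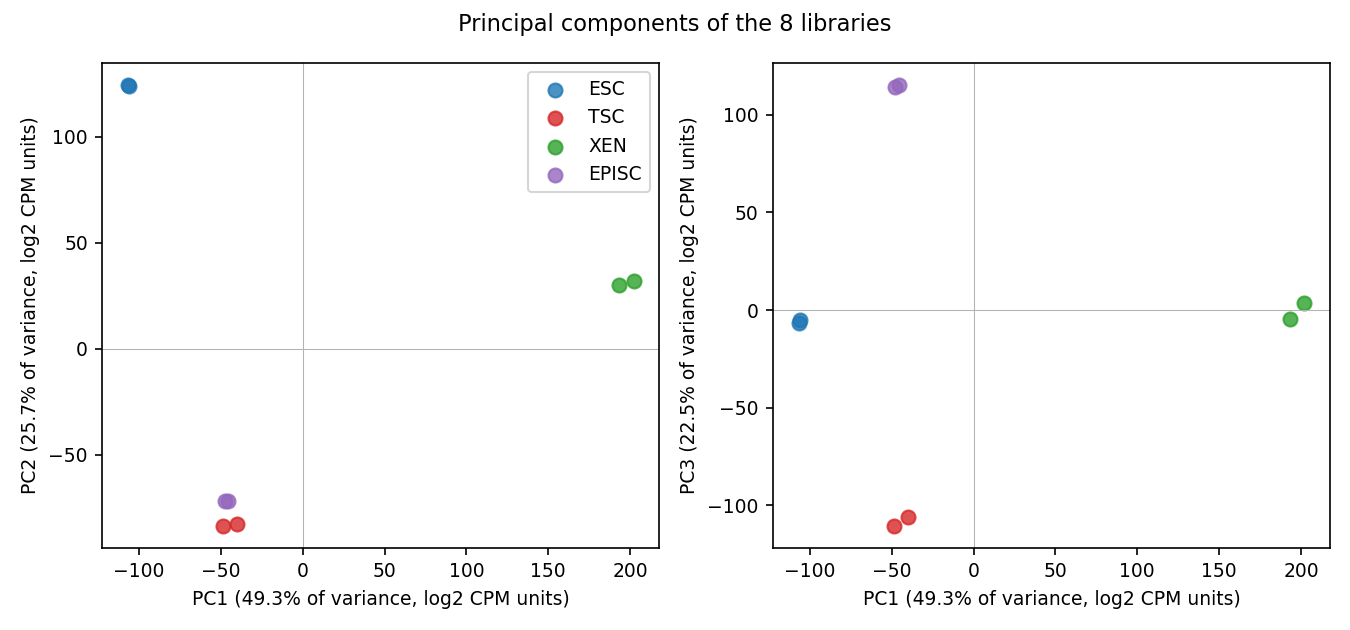
Principal components of log2 CPM over the 16169 tested genes, with 1 point per library coloured by line and the percent of variance on each axis. The 2 libraries of each line lie next to each other, XEN stands apart on the first component and ESC on the second.

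**Figure D2:**
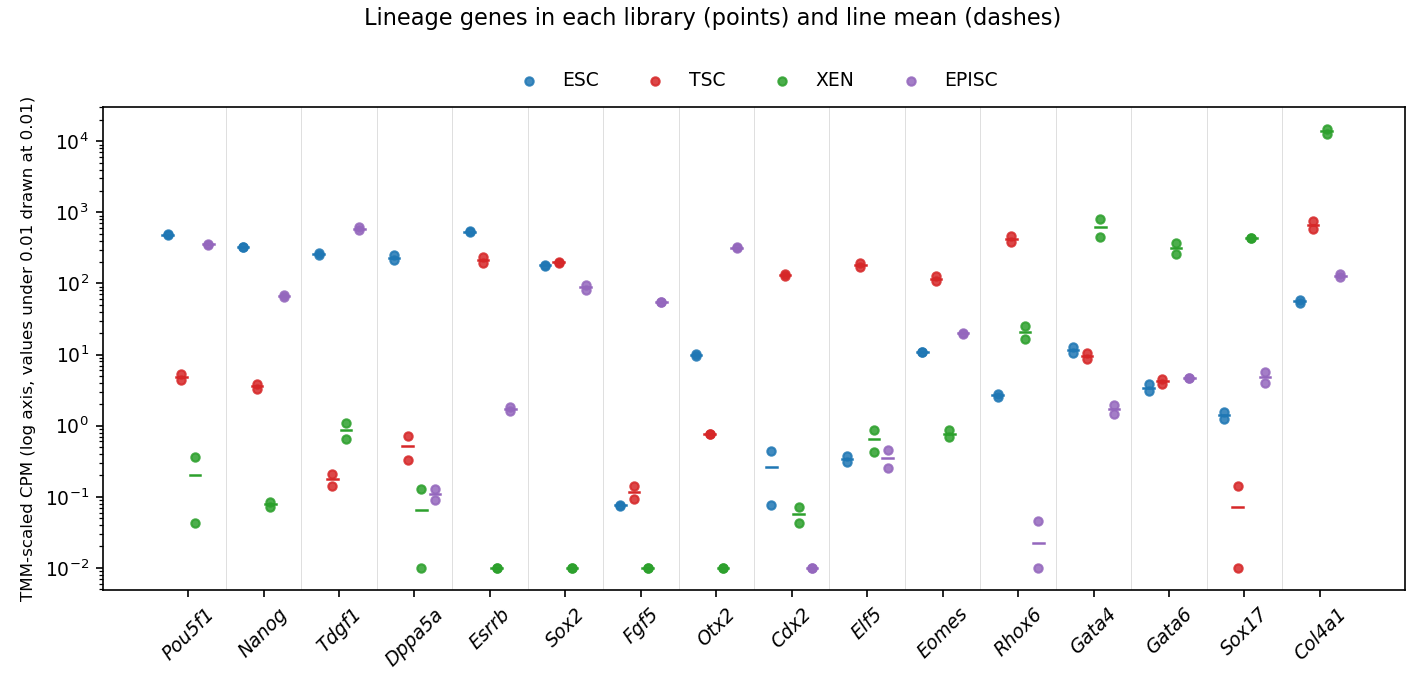
Level of lineage genes in each library in CPM on a log axis, with points for libraries and dashes for line means, and values under 0.01 CPM drawn at 0.01. Cdx2 is high in TSC, Sox17 in XEN and Fgf5 in EPISC, while Pou5f1 is high in ESC and EPISC.

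The comparison of TSC with ESC set the placental precursor against the pluripotent line. Genes of the trophoblast were higher in TSC. Cdx2 had a log2 fold change of 8.92 ± 0.32 (edgeR adjusted p = 1.82e-07), and Elf5, an ETS factor that holds cells in the trophoblast lineage, stood at 180.4 ± 17.3 CPM in TSC against 0.340 ± 0.0422 CPM in ESC. Pluripotency factors divided. Pou5f1 (log2 fold change -6.63 ± 0.21) and Nanog (-6.53 ± 0.14) were far lower in TSC, whereas Sox2 stood at 199 ± 5.27 CPM in TSC and 179.8 ± 4.15 CPM in ESC and was not called.

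Of the 18 tested trophoblast stem cell genes, 16 were called higher in TSC than in ESC and 1 lower (camera adjusted p = 2.40e-09, adjusted p = 0.0361 with an estimated correlation). Plac1, a gene of the placenta, had no count in ESC and was at least 490.4-fold higher in TSC, and Rhox6, a homeobox gene of the X chromosome, had a log2 fold change of 7.30 ± 0.27. Tfap2a was the member called lower (-1.53 ± 0.34). Of 17 tested genes of differentiated trophoblast, 16 were higher and none was lower (camera adjusted p = 1.41e-08, adjusted p = 0.0361 with an estimated correlation). Ctsq, a placental cathepsin, and Prl4a1, a placental prolactin, had no count in ESC and were at least 248-fold and 167-fold higher in TSC. Hand1, a factor of giant cells, stood at 137 ± 4.57 CPM in TSC and 0.569 ± 0.0724 CPM in ESC. Imprinted genes were higher in TSC for 11 of 19 and lower for 3 (camera adjusted p = 0.00489, adjusted p = 0.149 with an estimated correlation), led by the growth factor gene Igf2 (9.73 ± 0.29) and by Peg10 (7.59 ± 0.20), which reached 5313 ± 521 CPM. The maternally expressed RNA Meg3 (-2.87 ± 0.11), Plagl1 (-2.43 ± 0.19) and Nnat went the other way. Epithelial genes were higher in TSC for 10 of 15 with none lower (camera adjusted p = 0.000579, adjusted p = 0.186 with an estimated correlation), among them the keratins Krt8 (5.62 ± 0.28) and Krt18 (4.58 ± 0.14) and the tight junction gene Cldn3 (5.40 ± 0.36).

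Naive pluripotency genes, which mark the ground state of ESC, were lower in TSC for 10 of 18 and higher for 3 (camera adjusted p = 0.00315, adjusted p = 0.149 with an estimated correlation). Dppa5a (-8.72 ± 0.29), Prdm14 (-7.32 ± 0.47) and Nr5a2 (-5.79 ± 0.19) were among the lower ones, and Gbx2 (2.14 ± 0.31), Tex19.1 (2.10 ± 0.17) and Manba (1.88 ± 0.11) were the higher ones. Shared pluripotency genes were called lower for 6 of 13 and higher for 4, and the list was not called (camera adjusted p = 0.265, adjusted p = 0.392 with an estimated correlation). Tdgf1, a co-receptor of NODAL, fell from 259.7 ± 6.96 CPM in ESC to 0.176 ± 0.0496 CPM in TSC (-10.44 ± 0.22), while L1td1 (3.42 ± 0.25), Utf1 (2.13 ± 0.18), Trim71 (1.23 ± 0.10) and Dppa4 (1.15 ± 0.15) were higher in TSC. Germline genes were lower in TSC for 8 of 13 and higher for 2 (camera adjusted p = 0.0165, adjusted p = 0.392 with an estimated correlation), including the meiosis gene Hormad1 (-7.61 ± 0.33) and Dazl (-4.64 ± 0.20), with Tex101 (2.59 ± 0.28) and Taf7l (2.18 ± 0.26) against them. Genes of fibroblasts and feeder cells were higher in TSC for 9 of 14 and lower for 1 (camera adjusted p = 0.0221, adjusted p = 0.186 with an estimated correlation), among them Prrx1 (4.01 ± 0.24) and the collagen Col3a1 (2.63 ± 0.16), with Fbln5 lower (-2.50 ± 0.39). The immediate early genes Egr1 (4.24 ± 0.14) and Fosb (3.54 ± 0.21) were higher in TSC and the heat shock gene Hspa1a was lower (-4.75 ± 0.17), in a list that was not called (camera adjusted p = 0.541).

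In all, 3930 genes were called higher in TSC and 3737 higher in ESC, 47.4% of those tested, and with the size factors of DESeq2 the balance turned to 3720 and 3969. By the fixed rule for the largest folds, the leading genes higher in TSC were Ctsj, Ctsr, Prl2c5, Rtp4, Serpinb9e, Prl7d1, Plac1 and Prl7a1. None of these 8 had a count in ESC, and the bounds ran from at least 485-fold for Prl7a1 to at least 3036-fold for Ctsj, a placental cathepsin gene (chromosome 13, 61000179 to 61005959). The leading genes higher in ESC were A2m, Mcf2, Lrrc31, Platr10, Tdgf1, Ooep, Trim63 and Fkbp6. A2m and Mcf2 had no count in TSC and were at least 2922-fold and 1057-fold higher in ESC. The placental cathepsin, prolactin, serpin and Rhox genes have close relatives within their families, so the split of reads among members is uncertain. Of 26 lists tested, 7 were called in this comparison, 12 with DESeq2 and 13 when only the 4 libraries of the 2 lines were fitted, and only the 2 trophoblast lists held with an estimated correlation.

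The comparison of XEN with ESC set the endoderm line against the pluripotent one. Transcription factors of the primitive endoderm and genes of the basement membrane were higher in XEN. Gata6, which directs cells to this lineage, stood at 315 ± 73.1 CPM in XEN and 3.41 ± 0.541 CPM in ESC (6.52 ± 0.22, edgeR adjusted p = 2.12e-08). Col4a1, a chain of type IV collagen, reached 13768 ± 1689 CPM against 56.5 ± 3.74 CPM, and Lama1, a laminin chain, 13408 ± 1347 CPM against 215 ± 5.83 CPM. The core pluripotency genes Sox2 and Fgf4 had no count in either XEN library and were at least 2237-fold and 3307-fold lower than in ESC.

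Of 12 tested regulators of the primitive endoderm, 10 were called higher in XEN and none lower (camera adjusted p = 1.22e-12, adjusted p = 0.110 with an estimated correlation). Besides Gata6 they included Sox17 (8.27 ± 0.29), the receptor gene Pdgfra (7.79 ± 0.15) and Dab2 (9.18 ± 0.23), and the CPM of Sox7 in XEN and ESC stood in a ratio of 2589 (95% counting interval 716 to 21381). Genes of the parietal endoderm and its basement membrane were higher for 13 of 15 and lower for 1 (camera adjusted p = 6.02e-15, adjusted p = 0.117 with an estimated correlation), led by the plasminogen activator Plat (8.09 ± 0.16), Col4a1 (7.93 ± 0.21), the activin antagonist Fst (7.72 ± 0.18) and Pth1r (7.51 ± 0.31). The proteoglycan gene Hspg2 was the member called lower (-1.45 ± 0.28). Visceral endoderm genes were higher for 7 of 13 and lower for 3 (camera adjusted p = 0.00195, adjusted p = 0.196 with an estimated correlation). Cubn, an endocytic receptor, had a log2 fold change of 12.09 ± 0.19 and Hnf4a, a nuclear receptor, of 6.62 ± 0.28, whereas Apoa1 (-2.66 ± 0.34), Apoe (-1.71 ± 0.21) and Vil1 (-1.38 ± 0.22) were lower in XEN.

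Naive pluripotency genes were lower in XEN for 13 of 18 and higher for 1 (camera adjusted p = 1.06e-07, adjusted p = 0.196 with an estimated correlation). Esrrb, an orphan nuclear receptor, and Tcl1 had no count in XEN and were at least 6681-fold and 1119-fold lower, and Manba was the higher member (1.42 ± 0.11). Shared pluripotency genes were lower for 9 of 13 and higher for 2 (camera adjusted p = 0.000209, adjusted p = 0.196 with an estimated correlation). Pou5f1 had a log2 fold change of -11.50 ± 0.31, and the RNA-binding genes Lin28a (2.91 ± 0.10) and L1td1 (2.58 ± 0.25) were the higher members. Germline genes were lower in XEN for 12 of 13 with none higher (camera adjusted p = 2.74e-07, adjusted p = 0.252 with an estimated correlation), and Hormad1 and Mael, with no count in XEN, were at least 405-fold and 130.4-fold lower. Epithelial genes were lower for 10 of 15 and higher for 5 (camera adjusted p = 0.0379, adjusted p = 0.252 with an estimated correlation). The adhesion gene Cdh1 fell from 660.0 ± 8.89 CPM in ESC to 12.3 ± 0.0246 CPM in XEN and Cldn4 had a log2 fold change of -11.26 ± 0.41, while the keratins Krt8 (4.26 ± 0.26), Krt18 (2.80 ± 0.13) and Krt19 (3.73 ± 0.18) and the junction genes Cldn6 (1.96 ± 0.27) and Ocln (1.78 ± 0.14) were higher. Immediate early and stress genes were lower for 9 of 12 (camera adjusted p = 9.36e-05, adjusted p = 0.252 with an estimated correlation), among them Fos (-5.64 ± 0.16) and Fosb (-5.61 ± 0.28), with Atf3 higher (2.68 ± 0.13). Fibroblast and feeder genes were lower for 11 of 14 (camera adjusted p = 0.00117, adjusted p = 0.372 with an estimated correlation), with Postn and Col5a1 at no count in XEN and at least 553-fold and 433-fold lower. Neural genes were lower for 5 of 8 and higher for 1 (camera adjusted p = 0.0362, adjusted p = 0.372 with an estimated correlation), with Sox1 at least 104-fold lower and Tubb3 higher (1.58 ± 0.26). Of the Y-linked genes, Ddx3y had no count in XEN and was at least 1215-fold lower, and Xist, the RNA that silences an X chromosome, rose from 12.3 ± 1.26 CPM in ESC to 990.0 ± 171 CPM in XEN (6.33 ± 0.23). Their list was not called (camera adjusted p = 0.0726).

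A total of 3500 genes were called higher in XEN and 5318 higher in ESC, so 39.7% of the calls were higher in XEN. Leading the genes higher in XEN were Ugt2b34, Tfec, Cdh6, Cubn, Sox7, P3h2, Lpar3 and Robo2. Ugt2b34, a glucuronosyltransferase gene (chromosome 5, 86889767 to 86906937), and Tfec, a factor of the MITF family, had no count in ESC and were at least 1439-fold and 943-fold higher. The leading genes higher in ESC were Esrrb, Alpl, Fxyd6, Meg3, Fgf4, Laptm5, Fkbp6 and Sox2, all without a count in XEN, with bounds from at least 2237-fold for Sox2 to at least 6681-fold for Esrrb. Of the 26 lists 10 were called and none held with an estimated correlation. Without TSC replicate 2, which enters through the shared spread, 6 lists were called.

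The comparison of EPISC with ESC set the epiblast-like state against the earlier pluripotent state. Both lines held Pou5f1 at a high level and differed in genes of the naive and primed states. Pou5f1 stood at 486 CPM in ESC and 354 CPM in EPISC and was not called, and Tdgf1 rose from 259.7 ± 6.96 to 589.6 ± 34.4 CPM (1.18 ± 0.12, edgeR adjusted p = 3.16e-05). Otx2, a factor of the epiblast and anterior brain, rose from 9.95 ± 0.366 CPM in ESC to 319 ± 4.63 CPM in EPISC (5.00 ± 0.12). Esrrb, a factor of the naive state, fell from 537 ± 22.0 CPM to 1.74 ± 0.153 CPM (-8.26 ± 0.18), and Nanog was lower at 66.9 ± 2.17 CPM (-2.29 ± 0.11).

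Of 18 tested naive pluripotency genes, 16 were called lower in EPISC and 1 higher (camera adjusted p = 1.52e-10, adjusted p = 0.0690 with an estimated correlation). Tcl1 had no count in EPISC and was at least 1360.0-fold lower, Dppa5a had a log2 fold change of -10.95 ± 0.35, and the CPM of Zfp42, also called Rex1, stood in a ratio of 1945 (95% counting interval 665 to 9435) between ESC and EPISC. Nr5a2 was the higher member (2.53 ± 0.13). Genes of the formative and primed states were higher in EPISC for 12 of 14 and lower for 1 (camera adjusted p = 7.46e-06, adjusted p = 0.145 with an estimated correlation). The CPM of Fgf5 in EPISC and ESC stood in a ratio of 722 (95% counting interval 199.6 to 5964), and the de novo DNA methyltransferase gene Dnmt3b rose from 19.08 ± 0.312 to 509.6 ± 12.1 CPM (4.74 ± 0.11). Cdh2, which codes for N-cadherin, was higher (5.01 ± 0.39) and Fst was the lower member (-1.79 ± 0.16). Shared pluripotency genes went both ways, with 7 higher and 4 lower of 13, and the list was not called (camera adjusted p = 0.394). Dppa4 (-5.41 ± 0.21), Fgf4 (-3.63 ± 0.13), Nanog and Sox2 (-1.02 ± 0.12) were the lower ones.

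Targets of NODAL and TGF-beta signalling were higher in EPISC for 8 of 10 with none lower (camera adjusted p = 0.000286, adjusted p = 0.103 with an estimated correlation). Cer1, a secreted antagonist, had no count in ESC and was at least 276-fold higher, and the feedback inhibitors Lefty1 (6.02 ± 0.29) and Lefty2 (3.68 ± 0.17) were higher. Primitive streak genes were higher for 7 of 11, including Lhx1 (4.81 ± 0.41) and the T gene, which codes for Brachyury (3.78 ± 0.45), with Cdx1 lower, and the list was not called (camera adjusted p = 0.0653). Imprinted genes were higher for 11 of 19 and lower for 4 (camera adjusted p = 0.0212, adjusted p = 0.148 with an estimated correlation), with Mirg (4.34 ± 0.16) and Peg10 (3.95 ± 0.17) among the higher and Ascl2 (-2.60 ± 0.27), Slc22a18 (-1.53 ± 0.41), Dlk1 (-1.37 ± 0.47) and Igf2r (-1.28 ± 0.11) lower. Epithelial genes were higher for 9 of 15 and lower for 1 (camera adjusted p = 0.0379, adjusted p = 0.303 with an estimated correlation), with Esrp1 (3.16 ± 0.16) and Cldn6 (3.00 ± 0.27) higher and Cldn4 lower (-4.06 ± 0.24). Germline genes were lower in EPISC for 13 of 13 (camera adjusted p = 3.35e-08, adjusted p = 0.103 with an estimated correlation), with Mael and Taf7l at no count and at least 158-fold and 149.9-fold lower. All 16 tested Hox genes were lower in EPISC (camera adjusted p = 0.000231, adjusted p = 0.103 with an estimated correlation), and Hoxc8, with no count in EPISC, was at least 20.02-fold lower. Immediate early and stress genes were lower for 10 of 12 with none higher (camera adjusted p = 2.19e-06, adjusted p = 0.148 with an estimated correlation), among them Fosb (-6.51 ± 0.30) and Fos (-5.12 ± 0.16). Fibroblast and feeder genes went both ways, with 5 higher and 5 lower of 14 (camera adjusted p = 0.979).

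The test called 3794 genes higher in EPISC and 3502 higher in ESC, and with the size factors of DESeq2 3618 and 3648. Leading genes higher in EPISC were Gbp2b, Fndc3c1, Slc39a8, Kcnj3, Gbp2, Calcr, Sema3e and Fgf5. Slc39a8, a zinc and manganese transporter gene (chromosome 3, 135825279 to 135888572), rose from 0.676 ± 0.299 to 1792 ± 40.9 CPM (11.35 ± 0.22), and the interferon-inducible Gbp2b, whose sequence is close to that of Gbp2, had no count in ESC and was at least 1061-fold higher. Leading genes higher in ESC were Fkbp6, Ddx3y, Tcl1, Pmaip1, 4930447C04Rik, Sohlh2, Eif2s3y and Triml2. Fkbp6 and the germ cell factor gene Sohlh2 had no count in EPISC and were at least 2809-fold and 869-fold lower. Camera called 8 of the 26 lists and none held with an estimated correlation.

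The comparison of XEN with TSC set the extraembryonic lines against each other. Each line was higher in the genes of its own lineage. Sox17 stood at 434 ± 3.22 CPM in XEN with 3 counts over the TSC libraries, a ratio of 7170.0 (95% counting interval 2453 to 34772), and Lama1 had a log2 fold change of 9.72 ± 0.17 (edgeR adjusted p = 4.29e-09). Tfap2c, which codes for the trophoblast factor AP-2 gamma, and Hand1 had no count in XEN and were at least 3939-fold and 1706-fold lower than in TSC. Esrrb and Sox2, which TSC shares with ESC, had no count in XEN either and were at least 2725-fold and 2471-fold lower.

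Regulators of the primitive endoderm were higher in XEN for 11 of 12 with none lower (camera adjusted p = 4.06e-13, adjusted p = 0.0547 with an estimated correlation), including Sox7 (8.10 ± 0.21) and the forkhead gene Foxa2 (7.29 ± 0.29). Parietal endoderm genes were higher for 13 of 15 with none lower (camera adjusted p = 1.15e-12, adjusted p = 0.0616 with an estimated correlation), among them Fst (11.85 ± 0.22), Plat (4.95 ± 0.13) and the laminin gene Lamc1 (4.74 ± 0.12). Visceral endoderm genes were higher for 10 of 13 with none lower (camera adjusted p = 2.35e-07, adjusted p = 0.0616 with an estimated correlation), led by Cubn (10.35 ± 0.16) and Lrp2 (7.37 ± 0.13), and the CPM of Hnf4a stood in a ratio of 2161 (95% counting interval 598 to 17849). Trophoblast stem cell genes were lower in XEN for 16 of 18 with none higher (camera adjusted p = 4.06e-13, adjusted p = 0.0547 with an estimated correlation), and all 17 tested genes of differentiated trophoblast were lower (camera adjusted p = 3.53e-12, adjusted p = 0.150 with an estimated correlation). Bmp4 and the metalloprotease gene Mmp9 had no count in XEN and were at least 383-fold and 2081-fold lower, and Eomes had a log2 fold change of -7.27 ± 0.19.

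Epithelial genes were lower in XEN for 13 of 15 and higher for 1, Ocln (2.06 ± 0.14), in a list called lower (camera adjusted p = 4.73e-08, adjusted p = 0.0616 with an estimated correlation). Cldn3 had no count in XEN and was at least 2012-fold lower, and the splicing regulator Esrp1 had a log2 fold change of -9.72 ± 0.28. Imprinted genes were lower for 14 of 19 and higher for 2 (camera adjusted p = 8.90e-06, adjusted p = 0.142 with an estimated correlation), with Igf2 and Meg3 at no count in XEN and at least 2519.5-fold and 567-fold lower, and Plagl1 (2.82 ± 0.19) and H19 (1.89 ± 0.12) higher. Immediate early and stress genes were lower for 8 of 12 (camera adjusted p = 1.13e-05, adjusted p = 0.202 with an estimated correlation), and Fos stood at 1993 ± 324 CPM in TSC and 3.77 ± 0.363 CPM in XEN (-9.03 ± 0.18). Genes of fibroblasts and feeder cells were lower for 11 of 14 and higher for 1, Fbln5 (1.26 ± 0.43), with the list called lower (camera adjusted p = 3.75e-06, adjusted p = 0.202 with an estimated correlation). Col5a1 and Thy1 had no count in XEN and were at least 1002-fold and 325-fold lower. Naive pluripotency genes were lower for 12 of 18 and higher for 1 (camera adjusted p = 0.00275, adjusted p = 0.215 with an estimated correlation), with Klf2 lower (-6.59 ± 0.20) and Fbxo15 higher (4.21 ± 0.13). Germline genes were lower for 11 of 13 (camera adjusted p = 0.000415, adjusted p = 0.215 with an estimated correlation), and Mael was at least 45.4-fold lower. Hox genes were lower for 13 of 16 (camera adjusted p = 0.0124, adjusted p = 0.296 with an estimated correlation), and Hoxb4 was at least 25.1-fold lower. WNT target genes were lower for 8 of 12 (camera adjusted p = 0.00446, adjusted p = 0.149 with an estimated correlation), among them Lef1 and Cdx1, at least 24.6-fold and 38.1-fold lower. NODAL and TGF-beta targets were lower for 6 of 10 and higher for 2 (camera adjusted p = 0.0173, adjusted p = 0.215 with an estimated correlation), with Serpine1 lower (-9.02 ± 0.19) and Pitx2 (2.95 ± 0.15) and Tdgf1 (2.13 ± 0.38) higher. In the list of X inactivation and Y-linked genes, 4 of 5 were lower and Xist was higher (6.32 ± 0.23, camera adjusted p = 0.00401, adjusted p = 0.302 with an estimated correlation).

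This comparison gave 2445 genes higher in XEN and 4737 higher in TSC, a share of 34.0% higher in XEN. With libraries scaled by total counts alone the share was 22.1%, because that scaling lowered the median log2 fold change of all genes by a further 0.35. Among genes higher in XEN the leading ones were Ugt2b34, Spink1, Dpp4, Sox17, Fst, Tfec, Hnf4a and Srgn, and Spink1, a trypsin inhibitor gene, was at least 1180.5-fold higher. The leading genes higher in TSC were Ctsj, Tfap2c, Ddx3y, Esrrb, Sox2, Igf2, Mmp9 and Cldn3, with bounds from at least 2012-fold for Cldn3 to at least 4288-fold for Ctsj. Camera called 15 lists and none held with an estimated correlation.

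The comparison of EPISC with TSC set the embryonic epiblast state against the placental precursor. EPISC was higher in pluripotency genes of the shared and primed kinds, and TSC in genes of the trophoblast. Otx2 rose from 0.765 ± 0.0155 CPM in TSC to 319 ± 4.63 CPM in EPISC (8.69 ± 0.16, edgeR adjusted p = 1.17e-08), and Tdgf1 had a log2 fold change of 11.62 ± 0.23. Cdx2 and Rhox9 had no count in EPISC and were at least 1992-fold and 3549.5-fold higher in TSC. Sox2, like Dppa4, went against most shared pluripotency genes and was lower in EPISC, at 88.5 ± 10.6 CPM against 199 ± 5.27 CPM (-1.17 ± 0.12).

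All 18 tested trophoblast stem cell genes were lower in EPISC (camera adjusted p = 7.06e-15, adjusted p = 0.0197 with an estimated correlation), Gata2 among them (-10.51 ± 0.24), and 16 of 17 differentiated trophoblast genes were lower with none higher (camera adjusted p = 1.00e-11, adjusted p = 0.0197 with an estimated correlation). Ctsq and Prl3b1, a placental lactogen gene, had no count in EPISC and were at least 425-fold and 207-fold lower. Shared pluripotency genes were higher in EPISC for 9 of 13 and lower for 2 (camera adjusted p = 0.000211, adjusted p = 0.0824 with an estimated correlation), with Pou5f1 (6.17 ± 0.21) and Nanog (4.23 ± 0.13) higher and Dppa4 lower (-6.57 ± 0.21). Formative and primed genes were higher for 11 of 14 (camera adjusted p = 3.34e-06, adjusted p = 0.0541 with an estimated correlation), including Fgf5 (8.75 ± 0.25) and Sox3 (5.94 ± 0.43), and Pou3f1 was lower (-1.72 ± 0.26). Naive genes were lower for 15 of 18 and higher for 2 (camera adjusted p = 3.60e-06, adjusted p = 0.0824 with an estimated correlation), with Tex19.1 lower (-8.75 ± 0.27) and Nr5a2 (8.31 ± 0.19) and Fbxo15 (1.59 ± 0.13) higher. Neural genes were higher in EPISC for 6 of 8 and lower for 1 (camera adjusted p = 0.00182, adjusted p = 0.0824 with an estimated correlation), among them Stmn2 (5.84 ± 0.17), Map2 (5.43 ± 0.25) and Nes (2.50 ± 0.11), with Pax6 lower (-2.42 ± 0.36). NODAL and TGF-beta targets were higher for 5 of 10 and lower for 2 (camera adjusted p = 0.0251, adjusted p = 0.140 with an estimated correlation), with Lefty1 higher (5.60 ± 0.26) and Serpine1 (-3.86 ± 0.14) and Smad7 (-2.83 ± 0.14) lower. Visceral endoderm genes were higher for 6 of 13 and lower for 2 (camera adjusted p = 0.0323, adjusted p = 0.197 with an estimated correlation). Their higher members included Lrp2 (8.99 ± 0.14) and Cer1, which also belongs to the NODAL list and whose CPM stood in a ratio of 776 (95% counting interval 214 to 6416). Amn and Ttr, at 2.88 and 0.177 CPM in TSC, were the lower members.

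The other lists called were lower in EPISC than in TSC. Germline genes were lower for 11 of 13 (camera adjusted p = 1.48e-05, adjusted p = 0.0824 with an estimated correlation), with Taf7l at least 666-fold lower. All 16 tested Hox genes were lower (camera adjusted p = 1.17e-05, adjusted p = 0.0824 with an estimated correlation), among them Hoxa1 (-6.65 ± 0.39). Immediate early and stress genes were lower for 10 of 12 (camera adjusted p = 2.70e-07, adjusted p = 0.0950 with an estimated correlation), with Fosb (-10.05 ± 0.31), Fos (-8.51 ± 0.18) and Jun (-4.04 ± 0.17) among them. Fibroblast and feeder genes were lower for 9 of 14 and higher for 2 (camera adjusted p = 0.0168, adjusted p = 0.140 with an estimated correlation), with Prrx1 lower (-6.26 ± 0.28) and the smooth muscle genes Tagln (2.99 ± 0.48) and Acta2 (2.35 ± 0.15) higher. Mesoderm genes were lower for 5 of 7 (camera adjusted p = 0.0232, adjusted p = 0.140 with an estimated correlation), with the receptor gene Kdr (-6.23 ± 0.26) and Gata1 (-4.42 ± 0.22) leading. Parietal endoderm genes were lower for 8 of 15 and higher for 1 (camera adjusted p = 0.00810, adjusted p = 0.219 with an estimated correlation), with Thbd lower (-4.16 ± 0.21) and Fst higher (2.34 ± 0.22). Epithelial genes were lower for 6 of 15 and higher for 1 (camera adjusted p = 0.0242, adjusted p = 0.219 with an estimated correlation), with Cldn4 (-5.46 ± 0.25) and Krt8 (-3.10 ± 0.24) lower and Ocln higher (1.38 ± 0.14). Glycolysis genes were lower for 4 of 18 and higher for 2 (camera adjusted p = 0.0242, adjusted p = 0.394 with an estimated correlation), with the phosphofructokinase gene Pfkp (-3.21 ± 0.11) and the hexokinase gene Hk1 (-3.12 ± 0.11) lower and Pfkm higher (1.06 ± 0.11). Eno1, the other higher member (1.34 ± 0.35), shares reads with near-identical copies and its value is uncertain. Of X inactivation and Y-linked genes, 4 of 5 were lower and Xist was higher (6.17 ± 0.23, camera adjusted p = 0.00514, adjusted p = 0.249 with an estimated correlation).

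Calls were near balance in this comparison, with 3061 genes higher in EPISC and 2987 higher in TSC, and without TSC replicate 2 the numbers were 3081 and 3203. The leading genes higher in EPISC were Kcnj3, Trh, Platr10, Tdgf1, Calcr, Gria4, Tmem47 and Ugt8a. Kcnj3, a potassium channel gene (chromosome 2, 55435970 to 55598145), had no count in TSC and was at least 2393-fold higher, and Tmem47 had a log2 fold change of 9.40 ± 0.29. Those higher in TSC were Ctsj, Ddx3y, Rhox9, Cdx2, Eif2s3y, Rhox6, 4930447C04Rik and Ctsr, and Ctsr was at least 1207-fold higher. Of 17 lists called, the 2 trophoblast lists held with an estimated correlation.

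The comparison of EPISC with XEN set the epiblast state against the endoderm line. Genes of shared and primed pluripotency were higher in EPISC, and more genes of the endoderm and of naive pluripotency were higher in XEN than in EPISC. Otx2 and Fgf5 had no count in XEN and were at least 3965-fold and 679.8-fold higher in EPISC. Lama1 stood at 26.9 ± 0.208 CPM in EPISC against 13408 ± 1347 CPM in XEN (-8.96 ± 0.16, edgeR adjusted p = 4.41e-09), and Gata4, a zinc finger factor of the endoderm, at 1.70 ± 0.345 against 624 ± 241 CPM (-8.51 ± 0.35).

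Shared pluripotency genes were higher in EPISC for 10 of 13 with none lower (camera adjusted p = 1.69e-06, adjusted p = 0.125 with an estimated correlation), with Utf1 and Sox2 at no count in XEN and at least 1277-fold and 1104-fold higher. Formative and primed genes were higher for 11 of 14 and Fst was lower (-9.51 ± 0.20, camera adjusted p = 1.10e-05, adjusted p = 0.241 with an estimated correlation). NODAL and TGF-beta targets were higher for 7 of 10 with none lower (camera adjusted p = 6.77e-06, adjusted p = 0.135 with an estimated correlation), among them Tdgf1 (9.49 ± 0.20) and Lefty2, at least 525-fold higher. Primitive streak genes were higher for 9 of 11 and Foxa2, which is also on the endoderm list, was lower (-5.10 ± 0.24, camera adjusted p = 0.0131, adjusted p = 0.346 with an estimated correlation). Epithelial genes were higher for 11 of 15 and lower for 2 (camera adjusted p = 0.000940, adjusted p = 0.135 with an estimated correlation), with Esrp1 (10.12 ± 0.28) and Cldn7 (6.44 ± 0.31) higher and Krt19 (-2.05 ± 0.16) and Krt8 (-1.73 ± 0.23) lower. Neural genes were higher for 6 of 8 (camera adjusted p = 0.00105, adjusted p = 0.186 with an estimated correlation), with Neurod1 at least 62.5-fold higher. Genes of fibroblasts and feeder cells were higher in EPISC for 10 of 14 (camera adjusted p = 0.00105, adjusted p = 0.309 with an estimated correlation), and Twist1 was lower (-3.75 ± 0.46). Col5a1 was at least 1220.5-fold higher.

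Regulators of the primitive endoderm were lower in EPISC for 10 of 12 with none higher (camera adjusted p = 5.58e-12, adjusted p = 0.0907 with an estimated correlation), including Sox7 (-10.21 ± 0.25) and Pdgfra (-8.85 ± 0.16). Parietal endoderm genes were lower for 14 of 15 and Hspg2 was higher (1.13 ± 0.28, camera adjusted p = 1.24e-15, adjusted p = 0.0907 with an estimated correlation), with Fst, Lama1, Plat (-7.73 ± 0.15) and Col4a1 (-6.73 ± 0.20) the most lowered. Visceral endoderm genes were lower for 7 of 13 and higher for 2 (camera adjusted p = 0.00839, adjusted p = 0.241 with an estimated correlation), with Ttr at least 766-fold lower, Hnf4a lower (-9.83 ± 0.35) and Lrp2 higher (1.62 ± 0.09). Naive genes were lower for 9 of 18 and higher for 6 (camera adjusted p = 0.0349, adjusted p = 0.241 with an estimated correlation). In that list Nr5a2 (9.74 ± 0.22) and Esrrb, at least 21.7-fold, were higher in EPISC, and the CPM of Tbx3 stood in a ratio of 807 (95% counting interval 276 to 3918) in favour of XEN.

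EPISC had 4753 genes called higher and XEN 2496, so 65.6% of the calls were higher in EPISC. With total counts as the only scaling the share was 79.1%, with the median log2 fold change of all genes raised by 0.43, and the genes higher in XEN numbered 1576. The leading genes higher in EPISC were Igfbp3, Otx2, Meg3, Foxp1, Gbp2b, Adam23, Utf1 and Tcfl5, none with a count in XEN, and Igfbp3, which codes for an insulin-like growth factor binding protein, was at least 7567-fold higher. Those higher in XEN were led by Dpp4, Srgn, Ugt2b34, Grem2, Ttr, Vcam1, Pla2g12b and Tfec. Dpp4, a cell surface peptidase gene (chromosome 2, 62330073 to 62412231), stood at 443 ± 96.3 CPM in XEN with no count in EPISC, at least 6444-fold higher. Camera called 11 of the 26 lists and none held with an estimated correlation.

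**Figure D3:**
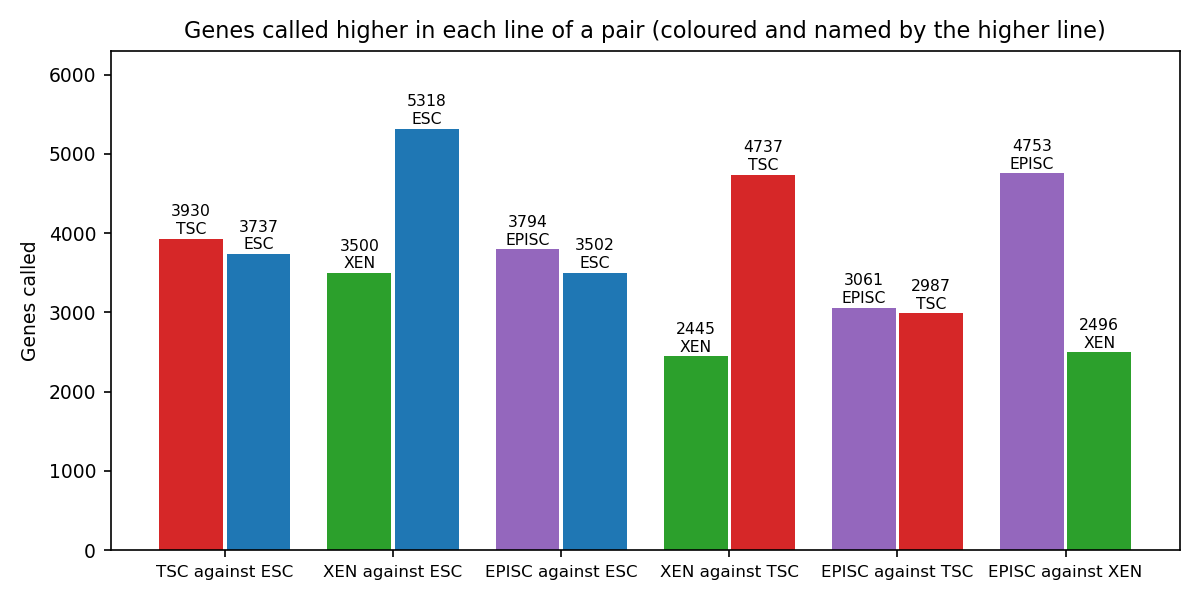
Number of genes called higher in each line of the 6 comparisons, with bars coloured and named by the higher line. The counts of the comparisons range from 2445 genes higher in XEN than in TSC to 5318 genes higher in ESC than in XEN.

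**Figure D4:**
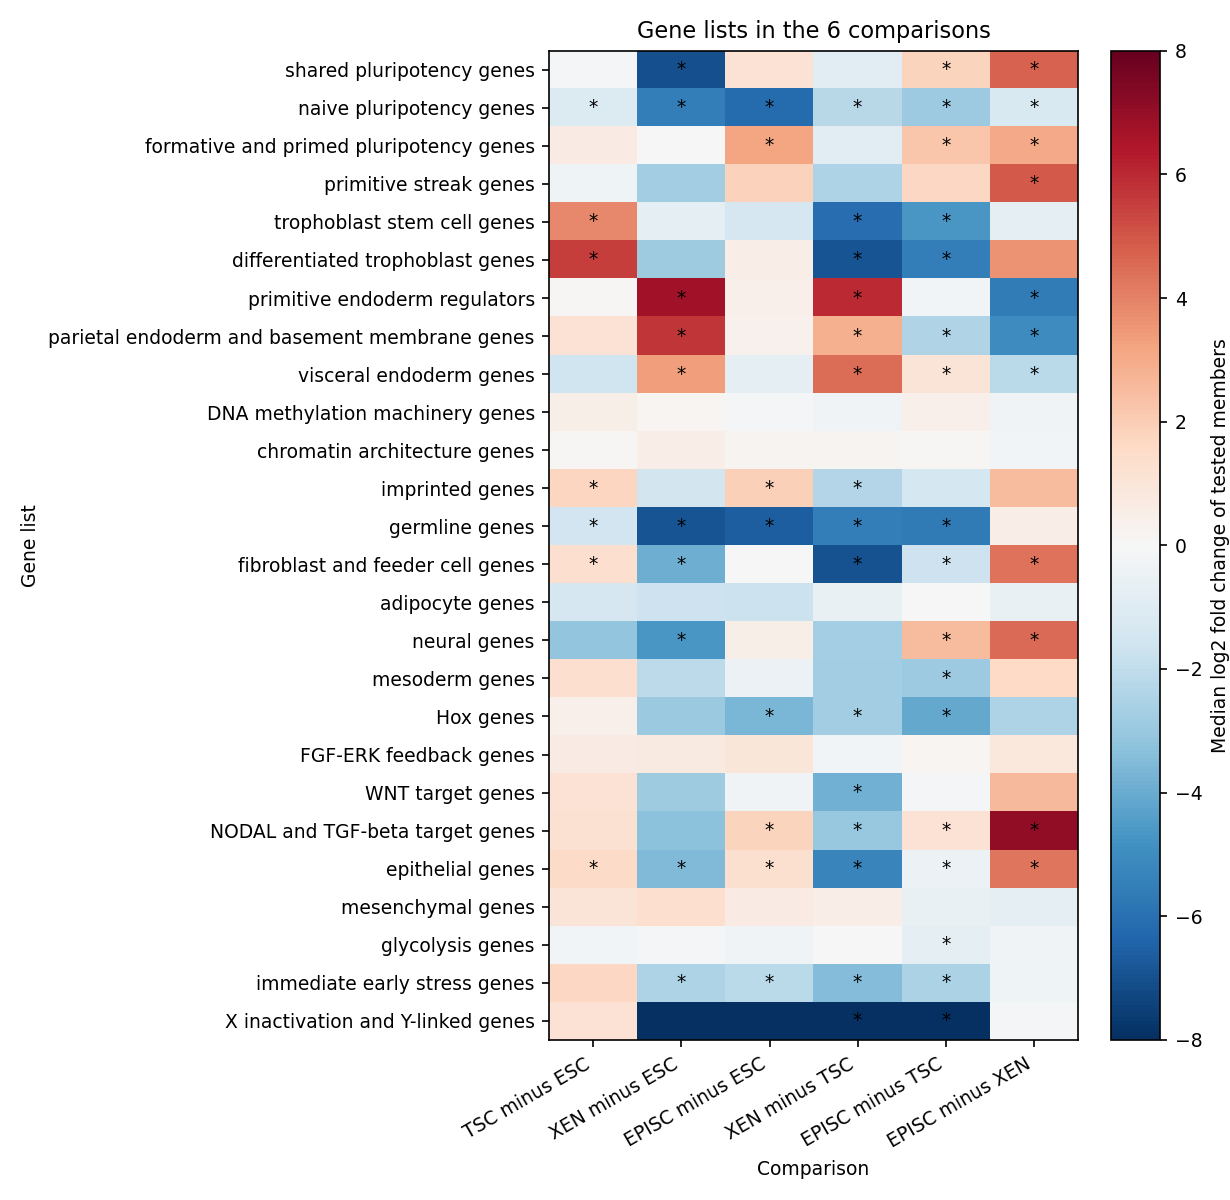
Median log2 fold change of each fixed gene list in the 6 comparisons, with genes at 0 counts set to their bound, colours saturating at 8 and an asterisk where the camera adjusted p was below 0.05. The 2 trophoblast lists are lower in XEN and EPISC than in TSC, and the endoderm lists are higher in XEN than in TSC and ESC.

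Several fixed lists were called in none of the 6 comparisons. The DNA methylation genes were divided, with 3 higher and 3 lower of 9 in TSC against ESC (camera adjusted p = 0.747), and Dnmt3l, a cofactor of de novo methylation, was lower in XEN than in ESC (-5.39 ± 0.15) while Dnmt3b was higher in TSC (4.36 ± 0.11), XEN (2.92 ± 0.11) and EPISC (4.74 ± 0.11) than in ESC. Of the 17 genes of chromatin architecture, which code for CTCF, cohesin and their partners, 5 were higher and 1, Brd4 (-1.65 ± 0.12), was lower in XEN than in ESC (camera adjusted p = 0.217), and Med1, a subunit of Mediator, was higher in TSC than in ESC (1.68 ± 0.11). FGF-ERK feedback genes were higher in TSC than in ESC for 6 of 13 with none lower (camera adjusted p = 0.0524), and in XEN against ESC 3 were higher and 4 lower (camera adjusted p = 0.573). In EPISC against ESC 6 were higher, among them Dusp6 (3.62 ± 0.13) and Spry4 (2.91 ± 0.16), and 2 were lower, Egr1 and Dusp4 (camera adjusted p = 0.0749). Of mesenchymal genes, Vim was higher in XEN than in ESC (4.06 ± 0.11) and Fn1 lower (-5.76 ± 0.13), and in XEN against TSC the median of the list was 0.56 and its mean -0.44, with camera in the direction of the median (camera adjusted p = 0.437). Of the 10 adipocyte genes 5 were tested, and 2 of these were lower in EPISC than in ESC (camera adjusted p = 0.250). Pparg was higher in TSC (7.54 ± 0.27) and XEN (6.96 ± 0.27) than in ESC, with Lpl lower in TSC (-3.08 ± 0.17). The list of the 2-cell-like state had 2 tested members and was not tested as a list, and Duxf3 was at least 8.005-fold lower in XEN than in ESC. The mitochondrially encoded genes were listed at 0 in all 8 libraries. Adjusted over the list alone, the numbers of called members equalled those above with the following exceptions. In TSC against ESC 6 rather than 5 mesenchymal genes were higher, and in XEN against ESC 9 rather than 8 trophoblast stem cell genes and 9 rather than 8 WNT targets were lower. In EPISC against XEN 1 rather than 2 germline genes were lower, and 2 Hox genes were higher and 4 lower rather than 3 and 5.

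The signatures gathered the genes called higher in a line than in each of the other 3. The ESC signature held 1826 genes, the TSC signature 1157, the XEN signature 1054 and the EPISC signature 1206. If the 3 lists behind each signature were independent, 266, 213, 81.7 and 211 genes would be shared. In 20 simulated data sets with no difference between lines no signature held a gene. A simulated comparison had at most 3 calls in a direction, so an empty overlap was nearly certain. The simulation therefore does not measure the overlap that shared libraries give to long lists. Each signature uses the 2 libraries of its line in all 3 comparisons, and these cannot be split, so part of the excess may come from the shared libraries. The ESC signature was led by Lrrc31, Ooep, Fkbp6, Tcl1, Dppa5a, Aim2, Trpm1, Morc1, A2m and Sohlh2. Dppa5a, a marker of naive cells (chromosome 9, 78367052 to 78368177), stood at 231 ± 25.6 CPM in ESC and at most 0.517 CPM elsewhere, and Morc1, a silencer of transposons in germ cells, at 200.4 ± 1.94 CPM and at most 1.04 CPM. The TSC signature was led by Ctsj, Ctsr, Prl2c5, Serpinb9e, Prl7d1 and Prl7a1, which had no count in the other lines, and by Cdx2, Elf5, Irx4 and Arhgef6. Elf5 (chromosome 2, 103411688 to 103450989) stood at 180.4 ± 17.3 CPM in TSC and at most 0.644 CPM elsewhere. The XEN signature was led by Ugt2b34, Tfec, Cdh6, Enpep, Cemip, Ttr, Sox7, Fst, Spock1 and Srgn. Fst (chromosome 13, 114452290 to 114458951) stood at 3572 ± 454 CPM in XEN and at most 16.9 CPM elsewhere, and Ttr, which codes for the thyroid hormone carrier transthyretin, at 50.4 ± 1.43 CPM. The EPISC signature was led by Kcnj3, Calcr, Fgf5, Frmpd2, Kcnq3, Gria4, Akr1c14, Thsd7a, Enpp3 and Zfp521. Fgf5 (chromosome 5, 98254184 to 98277030) and Calcr, the calcitonin receptor gene, stood at 54.6 ± 0.616 and 54.8 ± 3.58 CPM in EPISC.

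The shared sets asked which genes divide ESC and EPISC, which stand for the embryo proper, from TSC and XEN, which stand for its supporting tissues. ESC and EPISC together were higher than both TSC and XEN in 841 genes, and TSC and XEN together were higher than both ESC and EPISC in 436. Other pairings of the lines were not counted, so these numbers do not show that this divide is the largest. Across genes, log2 CPM correlated at 0.814 to 0.817 between ESC and EPISC and at 0.815 to 0.818 between ESC and TSC. The range was 0.838 to 0.847 between TSC and EPISC and 0.811 to 0.829 between TSC and XEN. Independent lists would share 68.4 and 24.3 genes and the simulated data sets gave none, and the same limits of the simulation and of shared libraries hold. The embryonic set was led by Platr10, Tdgf1, Pou5f1, Stmn2, Nmnat2, Dmd, Sfrp1, Nanog, Rimklb and Cth. Platr10, a long noncoding RNA of pluripotent cells (chromosome 3, 75647446 to 75655731), stood at 65.5 ± 3.99 CPM in ESC and 215 ± 3.87 CPM in EPISC, against 0.0353 CPM in TSC and 0.0428 CPM in XEN. Tdgf1 (chromosome 9, 110939603 to 110946158) and Pou5f1 (chromosome 17, 35506018 to 35510772) followed. The extraembryonic set was led by Nxf7, Rhox5, Cited1, Tfpi, Procr, Myo5b, Sfmbt2, Lhfpl2, Col6a1 and Meis1. Nxf7, an RNA export factor gene (chromosome X, 135579555 to 135598777), stood at 279 ± 23.8 CPM in TSC and 632 ± 80.9 CPM in XEN, against 1.14 CPM in ESC and 2.14 CPM in EPISC. Sfmbt2, an imprinted Polycomb gene needed in the placenta, stood at 753 ± 68.6 CPM in TSC and 525 ± 9.44 CPM in XEN, against at most 41.6 CPM in the embryonic lines.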

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

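The removal of the GC trend was chosen after the results were seen and the other alternatives before the data were examined. No called named gene and no called list changed direction under an alternative that tested it. Genes and lists that were not called in the main test were left out of this count of directions. The balance of higher against lower calls turned in 3 comparisons. TSC had 3720 and ESC 3969 genes higher with the size factors of DESeq2 in edgeR, and 3534 and 3662 with DESeq2 itself. EPISC had 3618 and ESC 3648 with these size factors, and 3391 and 3432 with DESeq2. EPISC had 4904 and TSC 5089 with adjusted p alone, 3081 and 3203 without TSC replicate 2, and 2883 and 2893 without EPISC replicate 2. Of 1518 calls of a named gene in a comparison, DESeq2 kept 1487, total counts alone 1471, the GC correction 1482 and glmTreat 1367, and leaving out a library kept between 1470 of 1518, without XEN replicate 2, and 1494 of 1518, without XEN replicate 1. The fit of 4 libraries tested 1438 of these calls and kept 1431, and the CPM filter tested 1471 and kept 1464. Of 68 list calls, fry, DESeq2 size factors in edgeR and total counts kept 68, limma-voom 58, DESeq2 60 and the GC correction 63, while an estimated correlation kept 4.

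With total counts alone, 1576 genes were higher in XEN than in EPISC and the XEN signature held 699, as that scaling moved the median log2 fold change of all genes by -0.26 in XEN against ESC, -0.35 in XEN against TSC, 0.43 in EPISC against XEN and 0.17 in EPISC against ESC. With adjusted p alone, which admits smaller folds, 5487 genes were higher in XEN than in ESC, 5332 in ESC than in EPISC, 4776 in XEN than in TSC, 4904 in EPISC than in TSC, 5089 in TSC than in EPISC and 4759 in XEN than in EPISC. The signatures then held 2852 genes in ESC, 1974 in TSC, 2501 in XEN and 1967 in EPISC, and the shared sets 1364 embryonic and 1235 extraembryonic genes. The stricter glmTreat gave 777 genes in the EPISC signature, 519 in the embryonic and 265 in the extraembryonic set. A log2 fold change of at least 2 gave signatures of 892, 563, 411 and 560 genes in ESC, TSC, XEN and EPISC. Without EPISC, and so with fewer comparisons to pass, the TSC signature held 1898 genes.

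Called lists in TSC against ESC numbered 12 with DESeq2 and 13 in the fit of 4 libraries, and the cause was not tested. With an estimated correlation, which takes the correlation among the genes of a list from the data, 2 lists were called in TSC against ESC, 0 in XEN against ESC, 0 in EPISC against ESC, 0 in XEN against TSC, 2 in EPISC against TSC and 0 in EPISC against XEN. With fry, which does not compare a list with other genes, the numbers were 22, 25, 20, 24, 24 and 19 in that order. Leaving out each library, the lists called in XEN against ESC ranged from 6 without TSC replicate 2 to 12 without ESC replicate 1, where the lone library is assumed to vary like the other lines, and the cause was not tested. Leaving out a library moved no count of genes by more than 1.5 times.

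Equal replicate numbers share only a number in the labels. Deviations of same-numbered libraries correlated at 0.085 for ESC and TSC, -0.10 for ESC and XEN, -0.41 for TSC and XEN, -0.058 for ESC and EPISC, -0.13 for TSC and EPISC and 0.14 for XEN and EPISC. With the replicate number as a block, 1504 of 1518 gene calls and 59 of 68 list calls were kept, and no count of genes moved by more than 1.5 times. Depth limits weakly expressed genes, since a line with no count was compared through 3 counts over its libraries. Of simulated 2-fold changes in TSC against ESC, 64.2% passed the adjusted p and 35.8% were called, since the fold minimum lies at the simulated fold.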

Other observations

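Gene families, chromosomes and the tests of sequencing depth, of a few genes taking many counts, of low-level RNA, of additional copies and of ESC RNA were chosen after the results were seen. Among 201 families of genes named by a common prefix, 12 of 1206 two-sided Fisher exact tests of a family in a signature or shared set passed Benjamini-Hochberg adjustment. These tests treat genes as independent, which members of a family that share reads are not, so the p-values may be too small. The prefixes Rpl and Rps of ribosomal protein genes, whose reads are shared with many processed copies, were frequent in the ESC signature. It held 31 of 49 Rpl genes (adjusted p = 2.4e-16) and 25 of 43 Rps genes (adjusted p = 4.7e-12). A prefix does not separate ribosomal protein genes from other genes whose symbols begin alike. Of 96 tested protein-coding genes with these prefixes, 73 were higher in ESC than in TSC, 66 than in XEN and 73 than in EPISC. Their median log2 fold changes were 1.49, 1.40 and 1.46, and with the GC trend removed the numbers were 73, 62 and 74. The TSC signature held all 13 tested prolactin genes (adjusted p = 1.1e-12), 9 of 11 interferon-inducible Ifi genes (adjusted p = 9.4e-07), 9 of 14 Serpinb genes and 8 of 11 Rhox genes. It held 11 of 373 Zfp genes, fewer than expected by chance. The EPISC signature held 10 of 35 cytochrome P450 genes.

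X-linked genes with at least 1 CPM, 486 in number, had a median log2 fold change of 0.45 in EPISC against ESC and 0.26 in XEN against ESC, where autosomal genes had medians of 0.05 and -0.02. In TSC against ESC the medians were 0.02 and 0.10, and in EPISC against XEN 0.05 and 0.04. X-linked genes numbered 91 in the EPISC signature where 42.6 were expected from the genes tested (Fisher exact test, adjusted p = 4.1e-10), 64 in the XEN signature where 37.1 were expected (adjusted p = 0.00040) and 61 in the TSC signature where 40.9 were expected (adjusted p = 0.010). Adjustment ran over all chromosomes and sets, and these tests too treat genes as independent. In the XEN signature some autosomes departed further. Chromosome 19 gave 79 genes where 35.6 were expected (adjusted p = 1.3e-09). Chromosome 16 gave 61 where 30.6 were expected (adjusted p = 6.3e-06). Fewer than expected came from chromosome 7, with 37 against 84.2 (adjusted p = 6.2e-08), and chromosome 17, with 23 against 52.4 (adjusted p = 8.2e-05). The ESC signature held 35 X-linked genes where 64.5 were expected (adjusted p = 0.00049). The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had no count in XEN or EPISC and were counted in ESC and TSC. Xist was higher in XEN than in ESC, and in XEN and EPISC than in TSC. The X-linked values of ESC, XEN and EPISC therefore cannot be told apart from a sex chromosome difference between the lines. The same holds for the Y-linked genes that led some comparisons. ESC and TSC both had counts of Y-linked genes, so such a difference is no full account of the X-linked excess in the TSC signature. The source of that excess was not tested. The Hox genes on the fixed list summed to 21.1 CPM in ESC, 32.6 CPM in TSC, 8.07 CPM in XEN and 1.10 CPM in EPISC. The 11 fibroblast genes lower in XEN than in TSC ranged from -6.26 for Prrx1 to 2.35 for Acta2 in EPISC against TSC, with an SD of 2.20. The predicted gene Gm26917 took from 0.117% to 1.10% of the counts of a library, and Lars2 took 0.391% in EPISC replicate 1 and 0.0499% in EPISC replicate 2. The difference between the 2 libraries of a line followed the GC content of transcripts across 11072 genes, with Spearman coefficients of 0.33 in ESC, 0.73 in TSC, -0.67 in XEN and -0.50 in EPISC, across genes that are not independent replicates. Removing that trend lowered the common biological coefficient of variation from 12.8% to 8.66%. On counts simulated for TSC against ESC with such a trend, the correction raised the calls from 126 to 150 of 194 changed genes and the false calls from 0 to 4.

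XEN had fewer genes with a count, 15057 and 15755, than any other library, and more genes called lower than higher against each other line. After thinning all libraries to the smallest total, XEN libraries held at most 14885 genes with a count and the other libraries at least 17787, with replicates differing by at most 172, which argues against depth. Without the 50 highest genes of each library the numbers were at most 14838 and at least 17626. For the number of genes with a count, this argues against a few genes that take many counts. For the split of calls, TMM scaling moved the medians of XEN by 0.26 to 0.43. It left at most 39.7% of calls higher in XEN, and at most 40.6% without any 1 library. The split was first seen with this same scaling, so these values are no separate test of a few genes taking many counts. Low-level RNA of other cells in the 3 other lines remains open, since calls higher in XEN made up at least 61.1% among genes at 50 CPM or more in the higher of both lines, but from 30.8% to 44.1% at 5 to 50 CPM and from 9.27% to 21.2% under 5 CPM. A line with fewer active genes at low levels predicts the same, and this biological difference between the lines was not tested.

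Genes of chromosomes 6, 16 and 19, which were picked after their medians were seen, were higher in XEN than the median of the other lines, with median log2 differences of 0.61, 0.74 and 0.62. The medians of the other autosomes ranged from -0.19 to 0.44, and with the GC trend removed chromosome 8 reached 0.54, next to 0.56 on chromosome 6. With the GC trend removed, the median of each of the 3 exceeded that of the other autosomes pooled by at least 0.42, which argues against GC content. Without that correction the lower quartile exceeded theirs by 0.42 on chromosome 6, 0.75 on chromosome 16 and 0.63 on chromosome 19. The lowest excess of a quartile or median in either library was 0.38. A few strongly raised genes would leave the lower quartile in place, so these values argue against them as the source on these 3 chromosomes. Because the chromosomes were picked by their medians, the values decide nothing about additional copies of these chromosomes in XEN, which stay open without DNA data, as does a regulatory difference between the lines.

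Sox2, Esrrb, Klf5 and Tfcp2l1, which are high in ESC, were also high in TSC, at 199 CPM, 216 CPM, 189.6 CPM and 456 CPM. If ESC cells or ESC RNA in the TSC libraries were the source, they would have to make up at least 40.3%, the level of Esrrb in TSC relative to ESC, which is the lowest among 10 listed genes at 50 CPM or more in both lines. Of 4445 genes at 50 CPM or more in ESC, 593 stayed below that share in TSC, or 13.3%, and Pou5f1, Nanog and Tdgf1 stood at 1.01%, 1.09% and 0.0679% of their ESC level. These values argue against ESC as the source of the pattern. No biological explanation was tested.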
